A study of Mus musculus with 11 samples.

How the data were processed

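HMCP-seq libraries, in which a capture kit enriches DNA fragments that carry 5-hydroxymethylcytosine (5hmC), were analysed from mouse embryonic stem (ES) cells and the epiblast-like cells (EpiLC) made from them. The 11 libraries came from a pair of wild-type parental lines named in the labels, TET_WT and DNMT_WT. TET_WT was sampled as ES cells grown in 2i/Lif (day 0, 3 libraries), at day 1 of EpiLC differentiation (2 libraries, numbered 2 and 3) and at day 2 (3 libraries). DNMT_WT was sampled at day 2 only (3 libraries). The knockout lines and the embryoid bodies that the series design names were not analysed here. The labels do not say whether the replicates were separate cultures, so p-values of tiles and genes measure only the spread between these libraries. The camera p-values of gene lists, described below, set genes against other genes. They do not measure how far a list would vary between new libraries.

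The submitters' processing notes name Trim Galore 0.6.5, cutadapt 2.3, Bowtie2 2.4.1 and the mouse build GRCm38. The deposited values are log2 RPKM as computed by the authors, that is the log2 of reads per kilobase of tile scaled to the read total of the library, in 1362779 tiles of 2 kb. The tool that counted reads per tile is not stated. Within each library the values were checked against whole read numbers, and 99.998% of them (rounded) lay within 0.1% of one in each library. Tiles without reads held the value of 0.9 reads. The reads recovered in this way came to 2.32 times the denominator of the deposited RPKM in each library, for a reason not known, which shifts all values of a library alike. RPKM is relative to the library total, so a change in the total amount of 5hmC per cell cannot be seen in these values.

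Recovered reads numbered 51604035, 29831998 and 49410704 in day 0 replicates 1, 2 and 3. They numbered 7342023 and 27484283 in day 1 replicates 2 and 3. The TET_WT day 2 libraries held 28084698, 20223140 and 27381625 reads in replicates 1, 2 and 3, and the DNMT_WT libraries 41395765, 16468363 and 29645990. The share of tiles without reads ran from 10.3% in day 0 replicate 3 to 31.8% in day 1 replicate 2, and the median from 2 to 15 reads per tile. Counting error therefore bounds what a single tile can show, and a gene value pools several tiles.

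Tiles on chromosomes 1 to 19 and X were kept (1316897). The 10% of tiles with the lowest and the 0.1% with the highest mean over all libraries were removed, which left 1183891. A gene was the annotated span in the GRCm38 gene table, extended by 2 kb on both sides because the table gives no strand. Its value was the mean log2 RPKM over its tested tiles, with at least 3 tiles. This gave 20717 of the 21631 protein-coding genes annotated. The design had set 2 kb upstream of the gene and promoter, exon and intron classes. The table allowed only tiles in a protein-coding gene, in another annotated gene only and outside annotated genes, besides autosomes and the X chromosome.

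Group means were compared with limma 3.58.1 in R 4.3.3 (with the package data.table, version 1.17.8), using lmFit and eBayes with a variance trend. All 11 libraries stood in one fit, because day 1 had only 2. The comparisons were day 1 and day 2 against day 0, day 2 against day 1, and DNMT_WT against TET_WT at day 2, each on tiles, genes and gene lists. Tiles were also compared between day 1 and the mean of day 0 and day 2. A call means a Benjamini-Hochberg adjusted p under 0.05, two-sided, over all tiles or genes of 1 comparison. The 12 gene lists held 252 entries, of which 248 could be measured. H19, Kcnq1ot1, Meg3 and Peg13 of the imprinted list are not protein-coding in the table. Dnmt3a, Dnmt3b, Sox7, Cdx2, Eomes and Hand1 each stand in more than one list. The lists, the comparisons, the tests and the rule for named genes were fixed before the data were examined.

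Lists were tested with limma's camera, which compares a list with all other genes, at its preset correlation of 0.01. Camera with the correlation estimated from the data and fry stand beside it. The p-value of fry tests whether a list's genes move on balance one way, and its mixed p-value whether they change in either direction. Neither compares the list with other genes. List p-values were adjusted over the 12 lists. Means over genomic classes and shares of reads were compared with exact permutation tests, two-sided, where 3 against 3 libraries cannot go below p = 0.1.

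Genes named per comparison were the 8 with the largest positive and the 8 with the largest negative difference among called genes whose groups do not overlap. Predicted genes and the olfactory and vomeronasal receptor families were left out. From each list came the 2 members with the smallest p and the member with the largest difference of the opposite sign. For day 2 against day 0 the rule added Tet1, Tet2, Tet3, Dnmt1, Dnmt3a, Dnmt3b, Dnmt3l, Tal1, Runx1, Gata1, Gata2, Zfp42, Esrrb, Nanog, Fgf5 and Otx2. Tiles were named as the 5 largest in each direction among called tiles whose groups do not overlap, at most 1 per 100 kb.

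Alternatives chosen beforehand were other tile filters, median centring, quantile normalization, log2(RPKM + 0.1), a replicate block, a fit of only the groups compared, no variance trend, a minimum of 2-fold, genes extended by 20 kb, the estimated correlation and leaving out each library. Tiles over the transcription start alone were not run, since the strand is not given. Added after the data were seen were limma voom on the recovered reads, thinning of every library to the 7342023 reads of the shallowest (equal depth) and chromosome centring, in which the median of each chromosome is set to the library's mean over chromosomes.

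The pipeline was tested on simulated data with the same depths and with genes changed by a known amount. Simulated tiles varied independently of each other, all with a dispersion of 0.0272. The simulation held no difference between libraries at gene level, such as that of day 0 replicate 2. Its rates therefore need not hold for the real comparisons with day 0. In day 2 against day 0, 75% of genes changed 2-fold and 56% of those changed 1.5-fold were recovered, with 5 false calls among 20013 unchanged genes. Voom recovered 95% and 83%, with 14 false calls. In single tiles 12.0% of 2-fold changes were recovered in that comparison. Unchanged simulated tiles gave 8 false calls there, but 607 false lower calls for day 1 against day 0, 1067 false higher calls for day 2 against day 1 and 2146 false lower calls for day 1 against the mean of day 0 and day 2.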

Results

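The signal of 5-hydroxymethylcytosine (5hmC), an oxidised form of methylated cytosine made by the TET enzymes, was profiled by capture and sequencing in 11 libraries of mouse cells. TET_WT cells were sampled as ES cells at day 0 (n = 3) and during conversion to EpiLC at day 1 (n = 2) and day 2 (n = 3). DNMT_WT cells, another wild-type line, were sampled at day 2 (n = 3). Libraries held between 7342023 and 51604035 recovered reads. Gene values are the mean log2 RPKM over the tiles of a gene, and differences are on the log2 scale with their standard error (SE) from the limma fit. Reads per gene differed between replicates by a chi-square per degree of freedom of 2.24 to 3.38 within the day 2 groups of both lines, and of 4.66 between day 0 replicates 1 and 3. Day 0 replicate 2 stood apart, at 30.4 against replicate 1 and 31.1 against replicate 3. The day 1 pair, whose replicate 2 held the fewest reads of all, had 2.16. This measure is taken from read counts and grows with depth, so it does not rank the day 1 pair against deeper pairs. Across genes, which are not independent replicates, the log2 values of that pair correlated at Pearson r = 0.949, against 0.957 for day 0 replicates 1 and 3 and 0.978 to 0.981 within the day 2 groups.

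Day 2 was compared with day 0 to ask where 5hmC changed at the exit from naive pluripotency. Genes of naive pluripotency gained signal: 19 of the 21 measured rose and 0 fell over all genes tested, and 20 rose adjusted over the list alone. Tbx3, a transcription factor of naive cells (GRCm38 chromosome 5, 119670534 to 119684724), rose from -2.83 ± 0.32 to 0.53 ± 0.06 log2 RPKM (SD, n = 3), a difference of 3.36 (SE 0.20, adjusted p = 1.79e-06). With voom it was 2.69. Klf2, a Krüppel-like factor of the same network, rose by 3.02 (SE 0.25, adjusted p = 1.5e-05). Nanog rose from -2.06 ± 0.51 to 0.65 ± 0.27 (difference 2.71, SE 0.25, adjusted p = 2.29e-05). Zfp42, known as Rex1 and a common marker of naive ES cells, rose by 1.56, Esrrb by 1.45 and Tdh, which encodes threonine dehydrogenase, by 1.78. In each of these 6 genes the 3 day 2 libraries and the 3 day 0 libraries did not overlap. Chance gives such a separation, counting both directions, in 10% of genes. Tbx3, Klf2 and Nanog stand among the largest gains, where non-overlap was a condition for being named, so it is no added support for them. The members without a call, named after their values were seen, were Nr5a2 (0.21, adjusted p = 0.123) and Nr0b1 (0.07, adjusted p = 0.948).

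The median difference of the naive list was 1.34, against 0.09 over all genes. Camera gave an adjusted p of 6.72e-17, with adjusted p = 0.00165 at an estimated correlation and 5.02e-07 by fry. It was the only 1 of the 12 lists called with an estimated correlation. The list stayed called under every alternative that was run. Day 0 replicate 2, which stood apart from its group, is part of this comparison, and the median was 1.43 without it.

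**Figure D1:**
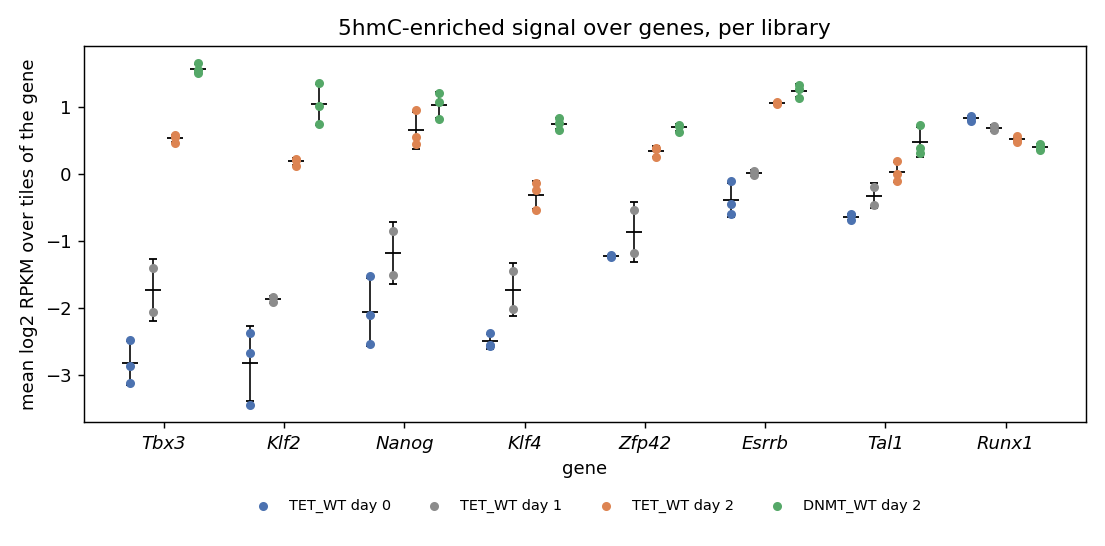
Mean log2 RPKM of each library (points) with the group mean and SD for 6 naive pluripotency genes and for Tal1 and Runx1, in TET_WT at day 0 (n = 3), day 1 (n = 2) and day 2 (n = 3) and in DNMT_WT at day 2 (n = 3). Tbx3 went from -2.83 at day 0 to 0.53 at day 2 in TET_WT, while Runx1 went from 0.83 to 0.52.

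Camera called 3 other lists at day 2, all higher. In the mesoderm and primitive streak list 9 of 20 genes rose and 0 fell by limma (12 and 0 adjusted over the list alone), against 11 and 1 with voom. Among those that rose were Hand1 (0.92, SE 0.11) and Foxf1 (0.78, SE 0.12), which act in mesoderm. In the neural list 7 of 20 rose and 0 fell (11 and 0 over the list alone), led by Olig2 (1.79, SE 0.22) and Pax6 (0.52, SE 0.09), while Sox21 did not pass (-0.14, adjusted p = 0.75). On tiles at or above the median signal only, Sox21 turned and was called higher (0.35, adjusted p = 0.0404). In the list of formative and primed epiblast 6 of 19 rose and 1 fell (7 and 1 over the list alone). Sall2 (1.28, SE 0.12), Etv5 (1.11, SE 0.13) and Otx2, a regulator of the primed state (0.69, SE 0.14), rose, and Utf1 fell by 0.63 (SE 0.18, adjusted p = 0.025). Fgf5, a marker of EpiLC, rose by 0.59 (SE 0.18, adjusted p = 0.043). Camera gave adjusted p = 0.00154 for mesoderm and 0.0123 for both the neural and the epiblast list. None of these 3 was called with an estimated correlation, where the adjusted p was 0.196, 0.196 and 0.101 in that order. Their median differences were 0.40, 0.41 and 0.29, against 0.38 for the housekeeping list, which camera did not call. Gains of this size were therefore not particular to these 3 lists.

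These calls had limits. The neural list missed the threshold without day 0 replicate 1 (adjusted p = 0.0504) and the epiblast list without day 0 replicate 3 (0.0522). Utf1 lost its call without day 0 replicate 3 (0.0656), day 2 replicate 2 (0.0783) or day 2 replicate 3 (0.107), and turned to 0.13 with voom. It also lost its call with tiles at or above the median signal only (-0.18, adjusted p = 0.378), median centring (0.231), quantile normalization (0.0644), chromosome centring (0.0567), equal depth (0.0519) and in genes extended by 20 kb (-0.042, adjusted p = 0.82). Fgf5 lost its call without day 0 replicates 1 or 2 (0.067, 0.0717), day 1 replicates 2 or 3 (0.0527, 0.0533), day 2 replicates 2 or 3 (0.152, 0.141) or DNMT_WT replicates 1 or 3 (0.0576, 0.0568), as well as with chromosome centring (0.169), equal depth (0.115), a fit of only the groups compared (0.0866) and no variance trend (0.0692). Otx2 lost it at equal depth (0.52, adjusted p = 0.0734). Pax6 and Foxf1 lost it with median centring (0.0788, 0.0532), although their differences were larger there, at 0.61 and 0.87.

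The hematopoietic list was examined because the study asks about priming for the blood lineage. Of its 30 genes 9 rose and 1 fell, both over all genes and adjusted over the list alone, and 20 did not pass. Lyl1, a helix-loop-helix factor of blood progenitors, rose by 0.72 (SE 0.10, adjusted p = 0.000432), Etv2, a regulator of blood and endothelial progenitors, by 0.99 (SE 0.18, adjusted p = 0.00234), and Tal1 by 0.67 (SE 0.14, adjusted p = 0.00612). Runx1 fell by 0.32 (SE 0.09, adjusted p = 0.0242), from 0.83 ± 0.04 to 0.52 ± 0.04 (SD, n = 3). Gata1 (0.05, adjusted p = 0.91) and Gata2 (0.28, adjusted p = 0.175) did not pass, although Gata2 did without day 0 replicate 2 (0.42, adjusted p = 0.0156) and with voom (0.00724). The list as a whole was not called by camera (median 0.23, adjusted p = 0.205; 0.304 with an estimated correlation), but was with voom (0.0309) and by fry (6e-05). Tal1 lost its call at equal depth (0.159) and Etv2 in genes extended by 20 kb (0.161). Runx1 lost its call without day 0 replicate 3 (0.0629) or without day 2 replicate 1, 2 or 3 (0.0932, 0.0601, 0.0809). With median centring Runx1 had -0.23 (adjusted p = 0.6), and it also lost its call with a fit of only the groups compared (0.0633), chromosome centring (0.0586) and equal depth (0.0641).

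Among genes of the DNA methylation machinery, 3 of 18 rose and 0 fell by limma, the same counts as adjusted over the list alone. With voom 5 were higher and 2 lower. Tet1 (0.68, SE 0.11), Tet2 (1.26, SE 0.23), which encode enzymes that make 5hmC, and Uhrf1, a cofactor of maintenance methylation (1.10, SE 0.16), rose, by 0.49, 0.53 and 0.74 with voom. Tet3 (-0.04), Dnmt1 (0.13), Dnmt3a (0.20), Dnmt3b (0.09) and Dnmt3l (0.33) had no call, with adjusted p of 0.87, 0.467, 0.267, 0.702 and 0.0712. Without day 0 replicate 2, Dnmt1 (0.0276), Dnmt3a (0.0107) and Dnmt3l (0.00982) passed, and Tet3 had a difference of 0.04. Dnmt3a (0.0131) and Dnmt3l (0.0197) passed with voom, and Dnmt1 (0.00321), Dnmt3b (0.0155) and Dnmt3l (0.000211) in genes extended by 20 kb. The list was not called by camera (adjusted p = 0.24; 0.304 with an estimated correlation). It was called by fry (adjusted p = 6.11e-05), as were 9 of the 12 lists in this comparison.

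The other 6 lists were not called by camera in this comparison. In the endoderm list 8 of 20 rose and 0 fell (8 over the list alone; camera adjusted p = 0.0511), including Trh (1.77) and Pdx1 (0.85). Trh gave -0.18 when extended by 20 kb, and Pdx1 lost its call with median centring (0.94, adjusted p = 0.0532). In the trophectoderm and extraembryonic list 8 of 20 rose, 1 fell (9 and 1 over the list alone; camera adjusted p = 0.0511), and Lama1, a laminin chain, fell by 0.68 (0.106 with median centring). Of 20 housekeeping genes 4 rose and 0 fell by limma (4 and 0 alone; 0.113), with Actb at 1.85 and Atp5b at 1.27, against 6 higher and 1 lower with voom. Of 20 germline genes none was called (0 over the list alone) with limma, against 2 higher and 5 lower with voom (camera adjusted p = 0.0511, median -0.09). Of 24 imprinted genes Igf2 rose by 0.45 and Igf2r fell by 0.49 (0 over the list alone; camera adjusted p = 0.0996). In the fibroblast and feeder list, markers of other cells a culture could hold, Thy1 alone of 16 rose by limma, by 0.54 (1 over the list alone; camera adjusted p = 0.649), against 2 higher and 2 lower with voom. Fn1 had 0.18 without a call, but -0.24 with a call by voom (adjusted p = 0.00278). Camera pointed down for that list, whose median was 0.11 and whose mean was 0.10.

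Several of these calls rested on 1 library. Without day 0 replicate 2 the endoderm and trophectoderm lists were called higher (both 0.00848) and the germline list lower (0.0259), so that 7 lists passed in place of 4. Without day 2 replicate 2 (0.046, 0.0318 and 0.046), DNMT_WT replicate 2 (0.0444 for all) or DNMT_WT replicate 3 (0.0457 for all) the same 3 lists passed. Endoderm and trophectoderm also passed without day 2 replicate 3 (0.027 and 0.0427), and endoderm without DNMT_WT replicate 1 (0.0499). Other settings moved lists across the threshold too: the replicate block called all 3 (0.0414, 0.0414 and 0.0493), as did a fit of only the groups compared (0.0479, 0.0479 and 0.0472), and median centring called the endoderm and housekeeping lists (both 0.0445). Igf2 lost its call without day 0 replicates 1 or 3 (0.0532, 0.129), day 2 replicates 1 or 2 (0.105, 0.151) or DNMT_WT replicate 1 (0.0568), and under most other settings, among them median centring (0.54, adjusted p = 0.171), equal depth (0.302) and voom (0.35). Igf2r lost it without day 2 replicate 1, 2 or 3 (0.0515, 0.0595, 0.0569) or with median centring (0.367), and Thy1 without day 2 replicate 2 or 3 (0.0657, 0.0511), with median centring (0.63, adjusted p = 0.108) or at equal depth (0.0689).

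**Figure D2:**
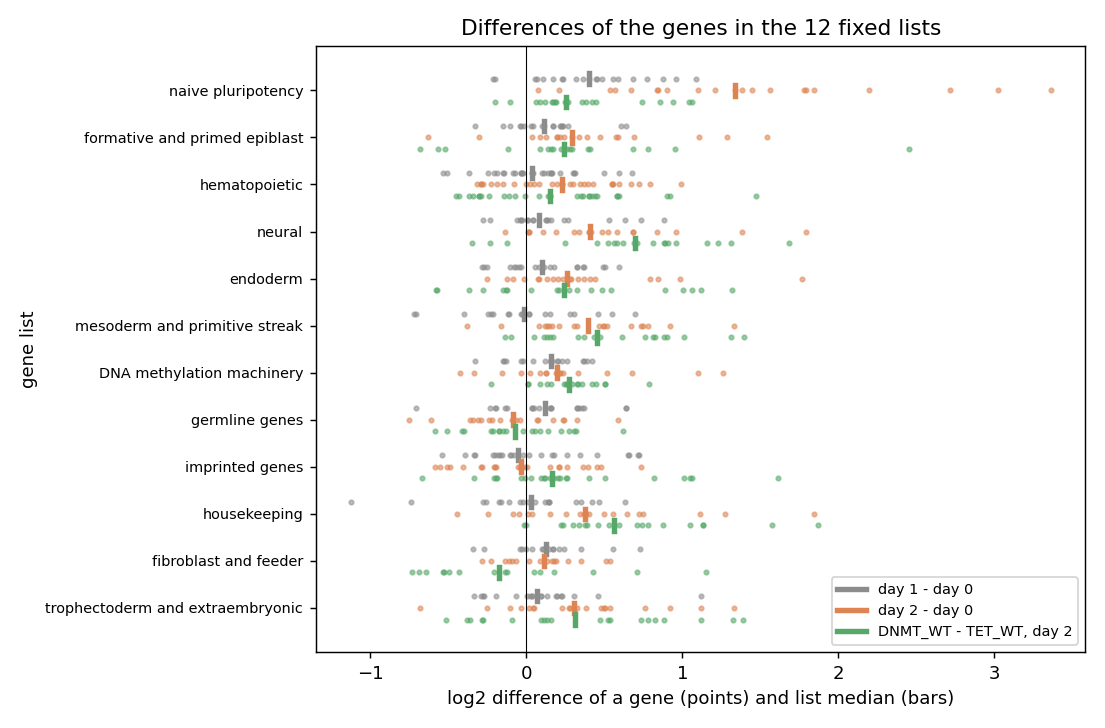
Log2 differences of the measured members of the 12 gene lists (points) with their medians (bars) for day 1 minus day 0, day 2 minus day 0 and DNMT_WT minus TET_WT at day 2. The median of the naive pluripotency list was 0.40, 1.34 and 0.25 in that order.

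Outside the lists, genes among the largest gains at day 2 were Aqp3, a water and glycerol channel (3.12, SE 0.19), Elf3, an epithelial transcription factor (2.78, SE 0.17), Tlx2 (2.57, SE 0.28) and Mylpf, a myosin light chain (2.48, SE 0.25). The largest losses were at Asmt, an enzyme of melatonin synthesis (-2.12, SE 0.18, adjusted p = 1.53e-05), Pramel14 (-2.04, SE 0.49), Pramel6 (-2.03, SE 0.22), Ly6c2 (-1.57, SE 0.33), Lce1c (-1.55, SE 0.45), Pf4, which encodes platelet factor 4 (-1.44, SE 0.15), Serpina3i (-1.44, SE 0.32) and Cyp2d11 (-1.39, SE 0.42). That the groups did not overlap was a condition for being named here, so it is no added support. Pramel14 lost its call without day 2 replicate 1 (0.0503), Ly6c2, Serpina3i and Lce1c at equal depth (0.0553, 0.139, 0.151), and Pf4, Ly6c2, Lce1c and Cyp2d11 in genes extended by 20 kb (0.4, 0.219, 0.232, 0.24). Lce1c lost its call without day 0 replicates 1 or 3 (0.111, 0.0922) or day 2 replicates 1, 2 or 3 (0.106, 0.0615, 0.0807), and with no tile filter (0.079) or no variance trend (0.0505). Cyp2d11 lost its call without day 0 replicates 1 or 2 (0.0622, 0.0727) or day 2 replicates 1, 2 or 3 (0.128, 0.0939, 0.0622), and with median centring (0.109), quantile normalization (0.0855), chromosome centring (0.0576), a fit of only the groups compared (0.0544) or no variance trend (0.0524).

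In single tiles the largest gains lay at Gm10069 (chromosome 6, 128460001 to 128462000, 6.70, SE 0.53), Pfdn1 (6.37, SE 0.61), a tile without an annotated gene on chromosome 2 (29552001 to 29554000, 6.37, SE 0.50), Cd9 (6.30, SE 0.37) and Klf4 (chromosome 4, 55528001 to 55530000, 6.19, SE 0.69). The Klf4 tile held 0, 1 and 0 reads in the day 0 libraries and 48, 39 and 34 at day 2. The largest losses lay on chromosome 8 outside genes (98628001 to 98630000, -4.50, SE 0.58), in Chn1 (-4.16, SE 0.82), on chromosome 10 outside genes (84744001 to 84746000, -3.91, SE 0.87), in Dnah6 (-3.81, SE 0.86) and in Nexmif on the X chromosome (-3.81, SE 0.52). The tiles that gained held 0 to 4 reads in each day 0 library and those that lost 0 to 5 in each day 2 library, so the sizes depend on the value given to tiles without reads. At equal depth the tiles in Chn1 (0.115), on chromosome 10 (0.172) and in Dnah6 (0.105) lost their calls.

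In all, 3689 of 20717 genes were called, 3170 higher and 519 lower. With voom 6898 were called, 3223 of them in common and 3221 of these with the same sign. Of 1183891 tiles 94794 were called, 63076 higher and 31718 lower (66.5% higher). Tiles numbered 11237 without a variance trend (84.4% higher), 17372 at equal depth (76.7% higher) and 63637 with median centring (80.7% higher). The gene count was 6543 without day 0 replicate 2 (4563 higher and 1980 lower, or 69.7% higher against 85.9%), 2264 without day 2 replicate 2 and 2414 without day 2 replicate 3. With median centring 1263 genes were called, 1207 higher and 56 lower.

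Day 1 was compared with day 0 and with day 2 to place the change in time. Over all genes none was called against day 0 by limma, with 2551 genes at an unadjusted p under 0.05 and 188 called with voom (109 higher, 79 lower). The naive list had positive differences at 19 of its 21 genes, with a median of 0.40. Its largest differences by p were at Prdm14, a transcription factor of naive and germ cells (0.68, SE 0.13, adjusted p = 0.0792), and Tbx3 (1.09, SE 0.22, adjusted p = 0.0907), against -0.22 at Tcl1. Adjusted over the list alone 8 of the 21 rose. Camera called this list (adjusted p = 2.39e-05), but not with an estimated correlation (adjusted p = 0.0532) or with voom (0.241). Tbx3 passed with voom (0.0158), in genes extended by 20 kb (0.0235) and without day 1 replicate 3 (0.0396), and Prdm14 passed without day 0 replicate 2 (0.0219).

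The other 11 lists were not called by camera at day 1, with adjusted p from 0.66 to 0.859, and had no member called over all genes by limma. Voom called 2 hematopoietic genes and 1 endoderm gene higher, among them Sox7, which stands in both lists (adjusted p = 0.00621). Adjusted over the list alone, 1 epiblast gene, 1 endoderm gene and 2 mesoderm genes rose, 2 mesoderm genes fell, and the other 8 lists had 0 of either. By fry 3 lists moved on balance one way: naive pluripotency (0.00432), formative and primed epiblast (0.0128) and DNA methylation machinery (0.0246). The mixed p-value of fry was lowest for the mesoderm list (adjusted p = 1.21e-06), whose genes went both ways. The hematopoietic list had a median of 0.03 and a mean of 0.04 with camera pointing down, and the germline list 0.12 and 0.10, also with camera down. For the imprinted list the median was -0.05 and the mean 0.06, and for housekeeping genes 0.03 and -0.0049, both with camera down. The shallow day 1 replicate 2, at 7342023 reads, and day 0 replicate 2 both enter this comparison. Without day 0 replicate 1, 2 or 3 the number of genes called was 3, 279 and 6, and without day 1 replicate 2 or 3 it was 1 and 46.

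From day 1 to day 2 the naive list rose: 15 of 21 genes passed and 0 fell (17 and 0 adjusted over the list alone), with a median of 0.79. Tbx3 rose by 2.27 (SE 0.22, adjusted p = 0.000138; 1.58 with voom) and Tdh by 1.29 (SE 0.14), while Nr0b1 had -0.38 (adjusted p = 0.672) and turned to 0.31 with day 1 replicate 2 left out. Camera gave adjusted p = 2.85e-13, and 0.00358 with an estimated correlation. In the mesoderm list 4 of 20 rose and 0 fell (10 and 0 alone), among them Tcf21 (1.24, SE 0.16) and Foxf1 (0.76, SE 0.13), with adjusted p = 3.47e-05, and 0.138 with an estimated correlation. In the neural list 4 of 20 rose and 0 fell (6 and 0 alone), including Olig2 (1.53, SE 0.25), with adjusted p = 0.0437, and 0.236 with an estimated correlation. The neural call was lost without day 0 replicate 2 (0.0609), day 0 replicate 3 (0.051) or day 1 replicate 3 (0.0882), with tiles at or above the median signal only (0.0674), with quantile normalization (0.0509), without a variance trend (0.0539) and at equal depth (0.0725). Extending genes by 20 kb ended the calls of Tdh (0.109) and Tcf21 (0.601), and median centring (0.219) and voom (0.119) that of Foxf1.

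The other 9 lists were not called between day 1 and day 2 by camera. Adjusted p was 0.0586 for the epiblast list (5 of 19 higher, 0 lower; 5 and 0 alone), with Etv5 at 1.21 and Foxd3 at 1.57. It was 0.06 for the hematopoietic list (4 of 30 higher, 0 lower; 8 and 1 alone), with Lyl1 at 0.79. It was 0.0586 for housekeeping genes (2 of 20 higher; 4 and 0 alone) and for trophectoderm genes (2 of 20 higher, 1 lower; 8 and 1 alone). The methylation machinery had 3 of 18 higher (3 and 0 alone; 0.532), among them Uhrf1 at 1.23. Endoderm had 1 of 20 higher, Trh (1 and 0 alone; 0.174), and fibroblast 1 of 16, Thy1 at 0.80 (1 and 0 alone; 0.432). Germline genes (0.0998) and imprinted genes (0.235) had 0 called by limma in either adjustment, against 0 and 1 with voom. Housekeeping genes passed without day 0 replicate 1 (0.0468), day 1 replicate 2 (0.00175) or day 2 replicate 1 (0.0251), trophectoderm genes without day 0 replicate 1 (0.0414) or day 2 replicate 2 (0.0343), and hematopoietic genes without day 1 replicate 3 (0.0379). Without day 2 replicate 3 these 3 lists and the epiblast list all passed (0.0497), as they did with no tile filter (0.0332 for all), with log2(RPKM + 0.1) (0.0334 to 0.0442) and with voom (0.0151 to 0.0264). The number of lists called was 5 without day 0 replicate 1 and 7 without day 2 replicate 3, and with voom it was 8. Fry called 9 of the 12. Thy1 lost its call without day 1 replicate 3 (0.0518) in genes extended by 20 kb (0.12), with median centring (0.125) and at equal depth (0.0558), Lyl1 with median centring (0.143), with voom (0.133) and at equal depth (0.0691), and Uhrf1 with median centring (0.0626). Under median centring these 3 had differences of 0.84, 0.83 and 1.26, no smaller than reported.

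The largest gains from day 1 to day 2 were at Rpp25 (2.84, SE 0.26), Aqp3 (2.47, SE 0.21), Spp1, which encodes osteopontin (2.41, SE 0.25), Gadd45b (2.36, SE 0.41), Pcolce (2.33, SE 0.19), Zfp36 (2.29, SE 0.36), Mylpf (2.28, SE 0.28) and Spata25 (2.28, SE 0.29). The largest losses were at Tas2r105 (-2.60), Tas2r104 (-2.42), Lce1c (-2.32), Mageb1 (-2.06), Mrgprb5 (-1.79), Tas2r136 (-1.73), Prss1 (-1.70) and Tex13c3 (-1.61). These 8 held a mean of 6 to 23 reads per library, and at equal depth each of them lost its call, with adjusted p from 0.0717 for Lce1c to 0.68 for Mrgprb5. Each also lost its call on leaving out at least 1 of the day 1 libraries, with adjusted p from 0.0535 for Mageb1 without replicate 3 to 0.299 for Tas2r104 without replicate 2. Tas2r105, Tas2r104, Mrgprb5, Tas2r136, Prss1 and Tex13c3 lost theirs without at least 1 of the day 2 libraries (0.0511 to 0.137), and the first 4 of these without at least 1 DNMT_WT library (0.0523 to 0.0689). With voom all 8 but Lce1c lost their calls. Zfp36 lost its call in genes extended by 20 kb (0.124). Voom gave smaller gains for Spp1 (1.68), Gadd45b (1.48), Pcolce (1.52) and Spata25 (1.63) and larger ones for Rpp25 (3.69) and Mylpf (3.21). Of 20717 genes 1986 were called, 1862 higher and 124 lower, and 988 with voom, 670 in common. Median centring gave 246 (236 higher, 10 lower). The count was 3568 without day 0 replicate 2 (3012 higher, 556 lower), 966 without day 1 replicate 2 (949 higher, 17 lower), 1058 without day 2 replicate 2 and 1169 without day 2 replicate 3.

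In single tiles 11957 were called at day 1 against day 0 (7116 higher, 4841 lower), and 35049 at day 2 against day 1 (28525 higher, 6524 lower). A tile outside genes on chromosome 2 (29552001 to 29554000) held 0, 2 and 0 reads at day 0 and 6 and 15 at day 1. A tile in Zfp57, a regulator of imprints, held 0 and 1 reads at day 1 and 48, 53 and 57 at day 2 (adjusted p = 0.0584 without a variance trend). Median tile differences were 0.19 for day 1 minus day 0 and -0.26 for day 2 minus day 1 as deposited, and close to 0 at equal depth, so tile directions are relative to those shifts. Without a variance trend 0 tiles were called by limma against day 0, where voom called 3647, and 16 from day 1 to day 2. A fit of only the groups compared called 860 higher and 2396 lower against day 0. The counts against day 0 were 3543 without day 1 replicate 2 (1713 higher, 1830 lower) and 24137 without day 1 replicate 3 (9664 higher, 14473 lower), so the prevailing direction depended on each day 1 library. The counts from day 1 to day 2 were 18231 without day 1 replicate 2 and 23000, 20451 and 23301 without day 2 replicates 1, 2 and 3. Equal depth gave 3676 (92.9% higher) and 5920 (41.4% higher).

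Against the mean of day 0 and day 2, 7228 tiles differed at day 1, with 1007 higher and 6221 lower by limma. Without a variance trend 0 were called, and voom called 311, of which 309 were higher and 2 lower. The tile with the largest positive difference lay outside genes on chromosome 6 (76328001 to 76330000), with 7 and 11 reads at day 1, 0, 1 and 1 at day 0 and 0, 0 and 0 at day 2, and lost its call without day 1 replicate 2 (adjusted p = 0.0724). The largest negative ones lay in C77080, with 1 and 0 reads at day 1, 25, 14 and 8 at day 0 and 96, 58 and 59 at day 2, and in Cdh3, which encodes P-cadherin, with 1 and 1 reads at day 1, 31, 29 and 32 at day 0 and 31, 25 and 36 at day 2. At equal depth 3887 tiles were called, 363 of them lower, and simulated libraries without change gave 2146 lower calls. The count was 3037 without day 1 replicate 2 (64 higher, 2973 lower), 20679 without day 1 replicate 3 (2858 higher, 17821 lower), and 4722, 4408 and 4704 without day 2 replicates 1, 2 and 3.

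DNMT_WT was compared with TET_WT at day 2 to see how far 2 wild-type lines of the same protocol differ, since each serves as the reference of its own knockout. Any difference of culture, library preparation or capture between the 2 sets of libraries cannot be told apart from one between the lines. Camera called 3 of the 12 lists, all higher in DNMT_WT. In the mesoderm and primitive streak list 12 of 20 were higher and 0 lower (13 and 0 adjusted over the list alone), among them Gsc, a homeobox gene of the organizer, at 1.66 ± 0.11 against 0.26 ± 0.07 log2 RPKM (SD, n = 3; difference 1.40, SE 0.12, adjusted p = 3.8e-05), and Hand2 (0.76, SE 0.08). Tbx5 had -0.14 without a call, but 0.30 with a call by voom (adjusted p = 0.00826). In the neural list 12 of 20 were higher and 0 lower (16 and 0 alone), with Sox1, a marker of neural progenitors, at 1.16 (SE 0.16) and Pax6 at 0.81 (SE 0.09). Of 20 housekeeping genes 6 were higher and 0 lower (6 and 0 alone), with Rplp0 at 1.87 (SE 0.24). Camera gave adjusted p = 3.57e-05, 4.41e-05 and 0.00303 for these lists. None was called with an estimated correlation, where the adjusted p was 0.121, 0.121 and 0.222.

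The hematopoietic list had 9 of 30 higher and 1 lower (12 and 1 alone). Lyl1 stood at 2.82 ± 0.12 in DNMT_WT against 1.35 ± 0.07 in TET_WT (SD, n = 3; difference 1.47, SE 0.10, adjusted p = 1.95e-05), and Epor, the erythropoietin receptor, differed by 0.92 (SE 0.11), while Ikzf1 had -0.45 (adjusted p = 0.158). Ikzf1 passed without day 0 replicate 2 (0.0463), with voom (0.00433), with a fit of only the groups compared (0.0302), without a variance trend (0.0405) and at equal depth (0.0271). The list was not called by camera (adjusted p = 0.303; 0.399 with an estimated correlation). It was called by fry (adjusted p = 9.29e-05), as were 10 of the 12 lists between the lines. The naive list had 5 of 21 higher and 0 lower by limma (5 and 0 alone; 0.0606), with Klf4 at 1.06 and Tbx3 at 1.04, against 8 higher and 1 lower with voom. Its call appeared without day 0 replicate 1 (0.0405), day 1 replicate 2 (0.0497) or day 1 replicate 3 (0.0478), and under several settings, from 0.00358 with chromosome centring to 0.0494 without a variance trend. Klf4 lost its call in genes extended by 20 kb (0.184).

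In the epiblast list 5 of 19 were higher and 2 lower (5 and 2 alone; 0.137). Sox3 had the largest difference (2.46, SE 0.25), which was 0.25 and without a call in genes extended by 20 kb (adjusted p = 0.51), as was Fst (0.78; 0.812 when extended, 0.165 at equal depth). Zic5 on chromosome 14 was lower (-0.68, SE 0.22, adjusted p = 0.0451). The endoderm list had 7 of 20 higher and 0 lower by limma (8 and 1 alone; 0.137), against 10 and 3 with voom. Its higher genes included the pioneer factors Foxa1 (1.07; 0.217 in genes extended by 20 kb) and Foxa2 (1.32). The trophectoderm list had 8 of 20 higher and 2 lower (10 and 3 alone; 0.137), with Ascl2, a trophoblast regulator, at 1.39. The methylation machinery had 3 of 18 higher (3 and 0 alone; 0.137), among them Dnmt1 at 0.51 (0.72 with median centring, where its adjusted p was 0.0661) and Tet1 at 0.42. Of 24 imprinted genes 5 were higher (5 and 0 alone; 0.415), with Cdkn1c, an inhibitor of the cell cycle, at 1.06 and Zrsr1 at 1.05 (0.127 at equal depth, 0.0596 with voom, 0.143 in genes extended by 20 kb, 0.0661 with chromosome centring and 0.184 with tiles at or above the median signal only). Of 20 germline genes 1 was lower (1 alone; 0.137), Piwil2 on chromosome 14 (-0.51), which lost its call with median centring (0.312) and had 0.13 with chromosome centring. The fibroblast list had 2 of 16 higher, Thy1 (0.71) and Twist1 (1.15), and 1 lower (2 and 1 alone; 0.137). With chromosome centring the epiblast (0.00688), endoderm (0.00915) and methylation machinery (0.0464) lists were called higher.

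Some of these calls depended on 1 library or setting. Zic5 lost its call without any 1 of day 1 replicates 2 or 3 (0.0577, 0.0583), TET_WT day 2 replicates 1, 2 or 3 (0.096, 0.15, 0.101) or DNMT_WT replicates 1, 2 or 3 (0.187, 0.057, 0.0514), and under most other settings, with -0.037 (adjusted p = 0.949) after chromosome centring. Tet1 lost its call without TET_WT day 2 replicates 1 or 2 (0.0815, 0.0639) or DNMT_WT replicates 1, 2 or 3 (0.0663, 0.053, 0.056), at equal depth (0.139) or with tiles at or above the median signal only (0.0529). Twist1 lost its call without TET_WT day 2 replicates 2 or 3 (0.0814, 0.0987) or DNMT_WT replicates 1, 2 or 3 (0.0834, 0.0501, 0.0845), in genes extended by 20 kb (0.473), at equal depth (0.069), with chromosome centring (0.065) or without a variance trend (0.0521). Thy1 lost its call in genes extended by 20 kb (0.133).

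The largest differences between the lines lay at single genes. Atf4, a factor of the stress response, stood at 1.01 ± 0.20 in DNMT_WT and -1.98 ± 0.16 in TET_WT (SD, n = 3; difference 2.99, SE 0.25). Otx1 (2.36, SE 0.21), Cbx8, a Polycomb subunit (2.36, SE 0.15), Hoxb7 (2.32, SE 0.17; 1.62 with voom), Ubqln2 (2.31, SE 0.49) and Fv1, a factor that restricts retroviruses (2.26, SE 0.32), were also higher. Pnp2 (-3.49, SE 0.32), Ang4 (-2.80, SE 0.26), Ear6 (-2.25, SE 0.56) and Pnp (-2.03, SE 0.21), all on chromosome 14, were lower, as were Ndufb4c (-2.94, SE 0.34), Lsm5 (-1.98, SE 0.34) and Krtap19-3 (-1.95, SE 0.59; -4.01 with voom). Defa30 was higher, and Duxbl1 on chromosome 14 lower, in DNMT_WT, but their tested tiles held no reads in the 3 libraries of TET_WT and of DNMT_WT respectively, so the size of their differences is not given. Otx1, Ubqln2 and Fv1 lost their calls in genes extended by 20 kb (0.489, 0.372, 0.284) and Lsm5, Ear6 and Krtap19-3 at equal depth (0.0709, 0.277, 0.189). Ear6 lost its call without TET_WT day 2 replicate 3 (0.0667) or DNMT_WT replicates 1 or 3 (0.0534, 0.0627), and with chromosome centring (0.0783). Krtap19-3 lost its call without TET_WT day 2 replicates 1 or 3 (0.149, 0.0947) or DNMT_WT replicates 1 or 3 (0.132, 0.104), in genes extended by 20 kb (0.0821) and without a variance trend (0.0635).

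Some tiles were nearly empty in one line. A tile that overlaps Miip and Fv1 (chromosome 4, 147868001 to 147870000) held 0, 0 and 0 reads in TET_WT at day 2 and 285, 105 and 251 in DNMT_WT. A tile in Tob2 (chromosome 15, 81858001 to 81860000) held 0, 3 and 4 reads against 676, 214 and 399. In the other direction a tile in Zfp978 (chromosome 4, 147224001 to 147226000) held 269, 210 and 288 reads in TET_WT and 0, 0 and 0 in DNMT_WT. The next 4 tiles all lay on chromosome 14. Among them, 1 in Rarb, the retinoic acid receptor beta gene, held 179, 121 and 122 reads against 0, 0 and 0. Another in Tcra held 163, 106 and 152 against 1, 0 and 0. Whether DNMT_WT holds the sequence of the tiles empty there was not tested, since no sequenced input DNA was used. The same limit holds for Duxbl1 and was not examined for the other genes named above. At day 0 the Miip and Fv1 tile held 8, 7 and 1 reads in TET_WT, and the Tob2 tile 13, 3 and 11.

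In all, 3929 of 20717 genes were called, 3086 higher and 843 lower in DNMT_WT, and 6649 with voom, 3512 in common and all 3512 with the same sign. Of the tiles 38415 were called, 11839 higher and 26576 lower (30.8% higher). Equal depth gave 1921 tiles, no variance trend 3288, chromosome centring 17313, and a fit of only the groups compared 67869 (44.6% higher), while voom gave 48.6% higher. Genes numbered 6215 without day 0 replicate 2 (4539 higher, 1676 lower), 2060 and 2459 without TET_WT day 2 replicates 1 and 3, and 2361, 2566 and 2472 without DNMT_WT replicates 1, 2 and 3. Tiles numbered 20126, 22335 and 21531 without TET_WT day 2 replicates 1, 2 and 3. The median tile difference was -0.12 as deposited and 0.09 with median centring, which gave 18549 tiles, 51.8% of them higher.

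Chromosome 14 held 354 of the 843 lower genes (42.0%), while 3.69% of the genes tested lie on it. Its share of reads was 3.55% ± 0.0156 in DNMT_WT and 5.44% ± 0.0279 in TET_WT at day 2 (SD, n = 3), a ratio of 0.653 (exact permutation p = 0.1, the smallest that 3 against 3 libraries allow). TET_WT had 5.33% ± 0.187 at day 0 and 5.65% ± 0.00994 at day 1. Each of its 24 windows of 5 Mb had a lower log2 ratio of reads scaled to the library total (RPM) than the 5th percentile of the windows of the other autosomes (-0.29), with a median of -0.64 and a range of -1.02 to -0.40. Without chromosome 14 the calls were 3082 higher and 489 lower. Of those 489, chromosome 6 held 126, against 45 higher genes, with a median difference of -0.15 over its 1094 genes and a ratio of read shares of 0.865 (exact permutation p = 0.1). Of the listed genes, Klf5, Tdh, Bmp4, Otx2, Zic2, Zic5, Sall2, Sox7, Sox21, Gata4, Apex1 and Piwil2 lie on chromosome 14.

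**Figure D3:**
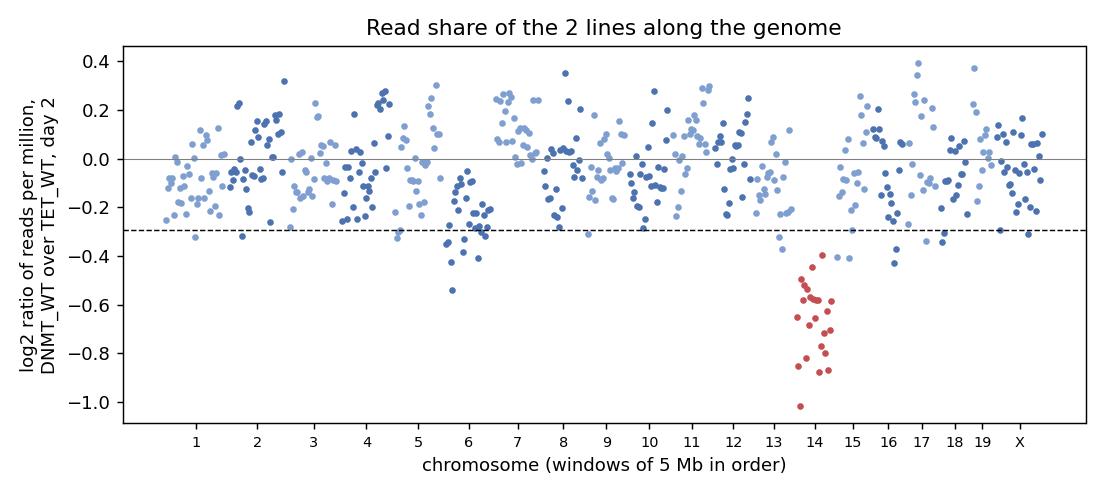
Log2 ratio of RPM in 5 Mb windows, DNMT_WT over TET_WT at day 2, along the chromosomes, with chromosome 14 in red and the 5th percentile of the other autosomes as a dashed line at -0.29. All 24 windows of chromosome 14 lie below the line, between -1.02 and -0.40.

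Mean signal over genomic classes was compared between day 0 and day 2 in TET_WT. Tiles in protein-coding genes had -0.87 ± 0.26 log2 RPKM at day 0 and -0.84 ± 0.01 at day 2 (SD, n = 3; exact permutation p = 1). Tiles in other annotated genes differed by -0.03 (exact p = 1), tiles outside genes by -0.06 (exact p = 0.9), autosomes by -0.02 (exact p = 1) and the X chromosome by 0.02 (exact p = 0.9), each less than the pooled SD of 0.18 to 0.25. These values depended on day 0 replicate 2. Without it, tiles in protein-coding genes differed by -0.12, those in other annotated genes by -0.17, those outside genes by -0.26 and autosomes by -0.19 (exact permutation p = 0.1 for each, the smallest possible), and the X chromosome by -0.14 (exact p = 0.3). Without day 0 replicate 1 or 3, autosomes differed by 0.040 and 0.086 (exact p = 0.7 for both). With no tile filter the X chromosome differed by 0.24 (exact permutation p = 0.1, the smallest possible), while the log2 ratio of its read share was -0.13. At day 1 tiles in protein-coding genes had -0.70 ± 0.15 (n = 2), and in DNMT_WT -0.95 ± 0.09 (n = 3). All these means include tiles without reads, whose set value depends on depth. That value ran from -5.63 log2 RPKM in day 0 replicate 1 to -2.81 in day 1 replicate 2, so class means and read shares can differ in direction. The share of reads in protein-coding genes was 56.9% ± 0.778 at day 0 and 58.6% ± 0.172 at day 2 (exact permutation p = 0.1). Outside genes it was 31.1% ± 0.991 and 30.1% ± 0.149 (exact permutation p = 0.3). In DNMT_WT the share in protein-coding genes was 60.2% ± 0.106 (n = 3), higher than in TET_WT at day 2, although its class mean was lower.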

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

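Equal depth and chromosome centring were chosen only after the results had been seen, and the rule on summed reads for chromosome 14 was set after both of its values were known. The tests of chance splits, leaving out libraries and simulated libraries were set beforehand.

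Reads outside the tiles tested gave signal in every group. Mitochondrial reads, as reads scaled to the library total (RPM), averaged 31.0 in TET_WT at day 0 (SD 22.4, n = 3), 24.3 at day 1 (SD 6.70, n = 2) and 3.24 at day 2 (SD 1.30, n = 3), and 56.7 in DNMT_WT at day 2 (SD 0.981, n = 3). At day 2 DNMT_WT had 17.5 times the mitochondrial RPM of TET_WT (exact permutation p = 0.1, the smallest possible). Reads on the Y chromosome averaged 263 RPM at day 0, 378 at day 1, 248.6 at day 2 and 282 in DNMT_WT. The tile with the highest signal (chromosome 2, 98666001 to 98668000), left out of the tests, averaged 7501 RPM at day 0, 3757 at day 1, 2058 at day 2 and 2187 in DNMT_WT. All of these lie above the RPM that a count of 3 reads gives in the shallowest library (0.409).

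Naive pluripotency genes had a median log2 difference of 1.34 between day 2 and day 0. Unequal depth would have at least halved it at equal depth, where it was 0.98 (spread 0.14). After chromosome centring it was 1.29 (spread 0.24). Shares of reads per chromosome changed little from day 0 to day 2. Their log2 ratios ran from -0.14 (chromosome 6) to 0.09 (chromosome 4) among the chromosomes tested. Shifts of this size are far smaller than 1.34, so centring could not have halved the median and is no separate test. Without day 0 replicate 2, the library that stood apart, the median was 1.43 (spread 0.27). The test of depth argues against depth as the whole cause. In a principal component analysis of gene values day 0 replicate 2 lay towards the day 2 libraries (-4.69, against -51.8 and -54.0 for its group). Its removal was therefore unlikely to halve the median, and shows only that the pattern does not rest on that library. A change of 5hmC with differentiation may underlie the pattern, as a hypothesis found and tested on the same data.

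Chromosome 14 carried less signal in DNMT_WT than in TET_WT along its length. If the change were confined to tiles of high capture signal, tiles below the median signal would lie above -0.2, but their median was -0.33 relative to other autosomes (SD 0.32 over 9 pairs of libraries, from -0.85 to 0.00), and their summed reads lay between -0.58 and -0.54 in the 9 pairs. A different copy number of chromosome 14 in the lines, lower in DNMT_WT or higher in TET_WT, is a candidate explanation, since 100% of its 24 windows lie below the 5th percentile of other autosomes. Which line would have changed was not tested. No sequenced input DNA was used here, so a chromosome-wide difference in 5hmC between the lines stays open and untested.

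Tiles lower at day 1 than the mean of day 0 and day 2 numbered 6221. At equal depth the count was 363, while that of higher tiles went from 1007 to 3524. Simulated libraries without change gave 2146 lower calls at these depths. Thinning removes reads, and lower calls at day 2 against day 0 also went from 31718 to 4047 at equal depth. The fall to 363 alone therefore cannot tell uneven depth from a loss of reads. The simulated calls are of the kind that uneven depth gives, so it may account for many of the lower tiles, as a hypothesis. No biological explanation was tested.

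Other splits of the 6 libraries into 3 and 3 were counted for day 2 against day 0 and for DNMT_WT against TET_WT. For day 2 against day 0, 1 of the 10 splits gave as many tiles (94794, highest other 0), 1 of the 10 as many genes (3689, highest other 0) and 4 of the 10 as many lists (4, highest other 7). The 3 other splits that reached 6 or 7 lists put day 0 replicates 1 and 3 together and apart from replicate 2. For DNMT_WT against TET_WT, 1 of the 10 splits gave as many tiles (38415, highest other 0), 1 of the 10 as many genes (3929, highest other 0) and 3 of the 10 as many lists (3, highest other 3). With 10 splits no share can be under 0.05.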

How the results depend on the processing

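Limma voom, equal depth and chromosome centring were chosen after seeing the data, and all other alternatives beforehand. Tiles over the transcription start alone were not run. Of the values for named genes under alternatives 4380 kept their sign and side of the threshold, 260 lost the call, 75 gained one and 58 changed sign. Of the list results 943 kept theirs, 10 lost the call, 77 gained one and 26 changed sign, all of the last at day 1 against day 0 in lists without a call. The named tiles kept theirs in 1047 cases and lost the call in 87. The naive pluripotency list kept its call at day 2 against day 0 and against day 1 under each setting. Genes near the floor are limited by depth: the median was 2 reads per tile in day 1 replicate 2 and 15 in day 0 replicate 1. Except where noted, the cause of the changes below was not tested.

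Filters changed some counts. With no tile filter 7 lists passed at day 2 against day 1, and the trophectoderm list at day 1 against day 0 changed direction (adjusted p = 0.928). The X chromosome then differed by 0.24 between day 2 and day 0 (exact permutation p = 0.1, the smallest possible), while the log2 ratio of its read share was -0.13. With tiles at or above the median signal only, fewer tiles were tested, and 7534 were called at day 1 against day 0 and 4096 against the mean of day 0 and day 2, besides 2 genes at day 1 against day 0. There the hematopoietic list changed direction at day 1 (0.988), as did Sox21 at day 2 against day 0 (0.35, called higher at adjusted p = 0.0404) and Dcx at day 2 against day 1 (0.19). The share of higher genes in DNMT_WT was 68.1%, against 78.5% as reported.

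Median centring gave 2439 tiles at day 1 against day 0, 18540 at day 2 against day 1 (93.9% higher, against 81.4%), 18549 in DNMT_WT (51.8% higher, against 30.8%) and 2796 at day 1 against the mean. For day 2 against day 0 it gave 63637 tiles, 80.7% higher in place of 66.5%. Genes numbered 1263 at day 2 against day 0 (1207 higher, 56 lower), 246 at day 2 against day 1 and 2553 in DNMT_WT (92.8% higher, against 78.5%), and 5 lists passed at day 2 against day 1. The trophectoderm list at day 1 (0.88) and 5 genes changed direction: Tet3 (0.0539), T (0.0193), Tfcp2l1 (0.0164), Tbx5 (0.0777) and Hprt (0.20). Quantile normalization gave 11244 tiles at day 1 against the mean. It turned Sox2 at day 1 (-0.12), the fibroblast list at day 1 (0.848), Cd34 (0.0595), Dcx (0.10) and Dcn (0.0448) at day 2 against day 1, and Hprt in DNMT_WT (0.14).

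With log2(RPKM + 0.1) 9 genes passed at day 1 against day 0 and 7 lists at day 2 against day 1, Sox21 turned to 0.0440, and 35.0% of the tiles at day 1 against the mean were higher, against 13.9%. The replicate block, with the replicate number as a term, gave 3 genes at day 1 against day 0 and 7 lists at day 2 against day 0, turned T to 0.0350 and the neural list at day 1 (0.947). It left all other total counts within 1.5 times, while lower genes at day 2 against day 1 numbered 75, against 124. Whether replicate numbers pair the libraries is not settled. Deviations from the group mean correlated best with the own number in 14 of 30 cases, each with only 2 or 3 libraries to choose from. Among 15 pairs of the same number the median correlation was 0.015, with 2 over 0.1. Among 30 pairs of different numbers it was -0.0049, with 7 over 0.1. A fit of only the groups compared, with fewer samples, gave 3256 tiles at day 1 against day 0, 3907 against the mean and 67869 in DNMT_WT, 6904 genes in DNMT_WT, and 7 and 5 lists at day 2 against day 0 and against day 1. The trophectoderm list turned there at day 1 (0.977).

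Without a variance trend 0 tiles passed at day 1 against day 0 and 0 against the mean with limma, while 11237 did at day 2 against day 0, 16 at day 2 against day 1 and 3288 in DNMT_WT, and 1170 genes at day 2 against day 1. A minimum of 2-fold, stricter by construction, left 62413 tiles at day 2 against day 0, and 558, 389 and 611 genes at day 2 against day 0, day 2 against day 1 and in DNMT_WT. Genes extended by 20 kb numbered 25 at day 1 against day 0, 3069 at day 2 against day 1 and 6262 in DNMT_WT. This turned Tcl1 (0.00393), Utf1 (0.10), Msgn1 (0.0544), Tex13b (0.0381) and Mcts2 (0.14) at day 1, Trh (-0.18) and Gata1 (-0.0713) at day 2 against day 0, Trh (-0.0292) and Ppia (0.23) at day 2 against day 1, and Magel2 (0.0552) and Hprt (0.16) in DNMT_WT. Camera with an estimated correlation called 0, 1, 1 and 0 lists at day 1 against day 0, day 2 against day 0, day 2 against day 1 and in DNMT_WT.

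Chromosome centring gave 3549 tiles at day 1 against day 0, 22174 at day 2 against day 1, 17313 in DNMT_WT and 2832 at day 1 against the mean. It gave 4 and 2333 genes at day 1 against day 0 and in DNMT_WT, and 7 lists both at day 2 against day 1 and in DNMT_WT. The neural and imprinted lists at day 1 (both 0.813) turned, as did Tet3 (0.0825), Nr0b1 (0.39), Dcx (0.34), Zbtb33 (0.23) and, by the removal of the shift of chromosome 14, Piwil2 (0.13).

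Equal depth gave 3676 tiles at day 1 against day 0 (92.9% higher, against 59.5%), 17372 at day 2 against day 0 (76.7%, against 66.5%), 5920 at day 2 against day 1 (41.4%, against 81.4%), 1921 in DNMT_WT and 3887 at day 1 against the mean (90.7%, against 13.9%). It has fewer reads by construction. At day 2 against day 1, 1059 genes passed. The hematopoietic (0.839) and trophectoderm (0.734) lists at day 1 turned, as did Sox21 (0.22), Tet3 (0.0286), Nr0b1 (0.0701), Cd34 (0.10), Dcx (0.0926) and T (0.0324).

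Voom gave 3647 tiles at day 1 against day 0 (79.1% higher), 7140 at day 2 against day 1, 311 at day 1 against the mean (99.4% higher) and, within 1.5 times the reported count, a share of 48.6% higher in DNMT_WT. Genes numbered 188 at day 1 against day 0, 6898 at day 2 against day 0 (73.6% higher, against 85.9%), 988 at day 2 against day 1 (79.8%, against 93.8%) and 6649 in DNMT_WT. It called 0 lists at day 1 against day 0, with 1 at an unadjusted p under 0.05 in the reported fit, and 8 at day 2 against day 1. At day 1 Utf1 (0.13), Msgn1 (0.15), Mcts2 (0.0207) and Sox2 (-0.37) turned, with the hematopoietic (0.882), mesoderm (0.944), fibroblast (0.882) and trophectoderm (0.882) lists. At day 2 Utf1 (0.13), Sox21 (0.19), Msgn1 (0.17) and Fn1 (-0.24, called lower at adjusted p = 0.00278) turned against day 0, Nr0b1 (0.32) against day 1 and Tbx5 (0.30, called higher at 0.00826) in DNMT_WT.

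Leaving out each library in turn gave 3543 to 24137 tiles at day 1 against day 0, 18231 to 45735 at day 2 against day 1, 20126 to 49959 in DNMT_WT and 3037 to 20679 at day 1 against the mean. Without day 0 replicate 2 the mean over autosomes differed by -0.19 between day 2 and day 0, against -0.023 as reported, and that over protein-coding genes by -0.12, against 0.028. Where leaving out a library left day 1 with 1 library, that library was assumed to vary like the other groups. Genes ran from 0 to 279 at day 1 against day 0, from 2264 to 6543 at day 2 against day 0, from 966 to 3568 at day 2 against day 1 and from 2060 to 6215 in DNMT_WT. Lists ran from 3 to 7 at day 2 against day 0 and from 2 to 7 at day 2 against day 1. At day 1 Mcts2 ran from -1.27 to 0.19 and Krt18 from -0.69 to 0.0234. At day 2 against day 0 Tet3 ran from -0.0872 to 0.0397 and Gata1 from -0.11 to 0.16. At day 2 against day 1 Nr0b1 ran from -1.07 to 0.31, Cer1 from -0.69 to 0.0128 and T from -0.0638 to 0.0464, and in DNMT_WT Hprt ran from -0.13 to 0.0887. Adjusted p at day 1 ran from 0.279 to 0.877 for the hematopoietic list, 0.28 to 0.91 for neural, 0.279 to 0.843 for mesoderm, 0.314 to 0.91 for germline, 0.0617 to 0.986 for housekeeping, 0.67 to 0.874 for fibroblast and 0.182 to 0.964 for trophectoderm.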

Other observations

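The Hox genes were singled out after their values were seen, and the comparison with random gene sets was chosen only then. Hox genes encode the transcription factors that pattern the body axis, in 4 clusters. In DNMT_WT at day 2, 37 of the 39 measured were higher than in TET_WT and 0 were lower, with a median log2 difference of 1.21 and Hoxb7 highest at 2.32. By cluster, 10 of 11 genes of Hoxa (chromosome 6, median 0.93), 10 of 10 of Hoxb (chromosome 11, 1.16), 9 of 9 of Hoxc (chromosome 15, 1.32) and 8 of 9 of Hoxd (chromosome 2, 1.52) were higher. From day 0 to day 2 in TET_WT, 26 of the 39 rose and 0 fell, with a median of 0.73.

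Random sets of 39 genes reached medians of at most 0.43 between the lines and 0.48 between the days in 10000 draws. Genes of a cluster are neighbours, so they are not independent and the draws are a description. Over 22 alternatives the median ran from 1.12 to 1.43 between the lines, with 33 to 38 genes higher, and from 0.51 to 0.82 between the days, with 15 to 28 higher. No Hox gene was called lower in any of them. Both comparisons use the TET_WT day 2 libraries, and whether the changes differ was not tested.

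In a principal component analysis of gene values the first component held 48.6% of the variance and the second 17.7%. On the first, day 0 replicates 1 and 3 lay at -51.8 and -54.0 and the day 1 libraries at -53.1 and -36.4. The TET_WT day 2 libraries lay at 5.16, 9.76 and 8.61, and the DNMT_WT libraries at 65.5, 49.8 and 61.1. Day 0 replicate 2, at -4.69, lay nearer to the TET_WT day 2 libraries than to its own group. On the second component it lay at 67.5, against 5.71 and -7.64 for the other day 0 libraries. The shallow day 1 replicate 2 lay at -43.6 there, against 6.72 for replicate 3.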
